A study of Mus musculus with 4 samples.

How the data were processed

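DNase-seq libraries of NK cells from female B6CASTF1/J mice aged 2 months were used, 4 in total, all in 1 group according to the cell type given in the labels. Each library has 2 peak lists, a list of bases with a low false discovery rate (FDR), a list of footprints and a readme. Per the deposited readmes, each file was derived by the authors from that library's own filtered alignments to mm10, so peaks were called per library and not on pooled libraries. The aligner, the peak and footprint callers, their versions and settings are not given in the sources used here.

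The authors' peak lists give 1 signal value per peak, per the file format, with constants in place of a score, p-value and summit. The deposited signal values were whole multiples of a step specific to each library, within 0.05 of a step for 100% of peaks. The step was 0.0118, 0.0101, 0.00831 and 0.00961 in replicates 1 to 4. The number of reads is not given in the files. If 1 step stood for 1 cut scaled by library size, replicate 3 would be the most deeply sequenced library and replicate 1 the least, but the unit is not stated, so no counting interval is given and signals of different libraries are compared only with that limit. The deposited FDR values, used here as p-value or q-value like measures, list bases from 0 to just under 0.05. Every peak of the shorter list held a base with an FDR below 0.001, and 72.5% ± 1.71 of the peaks of the longer list did (SD, n = 4). The longer list, with 49266 ± 14075 peaks per library, was used, and the shorter list, with 35056 ± 11081, is an alternative. The authors' footprints carry a constant of 0.01 in the p-value column, read as their threshold, so no stricter footprint set could be made.

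Gene positions came from GENCODE vM21 on GRCm38.p6, the same assembly as mm10, and protein-coding genes on chromosomes 1 to 19 and X were used. Peaks of the 4 libraries that touch or overlap were merged. A region was called promoter if any part of it lay within 1 kb of the 5' end of a protein-coding gene and distal otherwise, and recurrent if at least 3 of 4 libraries had a peak. The promoter signal of a gene is the highest peak signal within 1 kb of its 5' end, taken as 0 without a peak. Overlap of peaks, found with bedtools, required 1 bp, and chance levels came from 20 circular shifts per pair.

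Fixed before the data were examined were 12 gene lists, 4 of them for NK cells (receptors and adaptors, cytotoxic effectors and secreted factors, transcription factors, cytokine receptors and trafficking) and 8 others (ILC2 and ILC3, T cell, B cell and plasma cell, myeloid and dendritic cell, erythroid and megakaryocyte, stromal, endothelial and epithelial, tissues outside blood, housekeeping). Each list was compared with protein-coding genes in no list by Fisher's exact test, and the pooled NK lists with each other list, all two-sided with Benjamini-Hochberg adjustment at 0.05. Distal regions per locus (gene body and 25 kb on either side) were compared with 10000 random lists matched on locus length in 20 bins. Sharing of promoter and distal regions was tested by flipping the sign of chromosome differences, 100000 resamples over 20 chromosomes. These tests describe the 4 libraries, with genes, regions or chromosomes as the units.

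Motifs were 28 fixed consensus sequences. Windows of 150 bp at the centre of distal recurrent regions were compared with equal numbers of windows outside peaks, matched on chromosome and on GC content in 2% bins. Footprint ratios divide the share of motif matches lying at least 80% in a footprint by the share of bases in a footprint. Genes named in the text follow a rule fixed beforehand. It takes the up to 4 members of each list with the highest mean promoter signal among those with a peak in all 4 libraries, every NK list member with no promoter peak in any library, the 4 members of each NK list with the most distal regions, and the 10 genes with the most distal regions and the 10 with the highest promoter signal. The Y-linked genes and their X-linked partners, Xist, and genes open only at another transcript start were added after their values were seen.

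The tests were tested on simulated data. With lists planted at 90% open promoters against 50%, 95.7% of planted lists and 1.00% of other lists were called in 100 simulations of 21728 genes. The planted share is above that of each NK list in the data, the highest being 80.0%. How often lists at the observed shares would be called was not simulated. With a planted locus ratio of 2.5, 73.3% of planted lists and 0.370% of others were called in 30 simulations. The mean recovered ratio was 2.27 ± 0.492 (SD), somewhat below the planted one. Locus counts were drawn independently for each gene, so overlap between loci of neighbouring genes was not simulated. A motif written into 5% of 7983 windows rose from 1.85% to 6.78% of windows, with 0 other motifs called. Of 400 null sets, 6.00% passed the sign-flip test.

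Alternatives were the shorter peak list, an equal number of the strongest peaks per library, reciprocal overlap of 50%, promoter windows of 500 bp and 2.5 kb, any transcript's 5' end, presence in at least 1 or in all 4 libraries, locus flanks of 0 and 50 kb, windows of 300 bp or 1 kb to either side, footprint overlaps of 1 bp and 80%, and leaving out each replicate in turn, with recurrence then meaning all but 1 of the remaining libraries. Chosen after the data were seen were 5' ends of all annotated genes, any transcript's 5' end for sharing, matching on signal, and a motif-length expected share for footprints. Work was done in Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, matplotlib 3.10.9 and bedtools 2.31.1.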

Results

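Open chromatin was profiled by DNase-seq in natural killer (NK) cells, the cytotoxic lymphocytes of the innate immune system. DNase-seq reads out the positions at which the nuclease DNase I cuts chromatin, so that dense cutting marks accessible DNA. The cells were primary cells of female mice aged 2 months of the strain B6CASTF1/J, an F1 cross of C57BL/6J with CAST mice. The 4 libraries were labelled as biological replicates 1 to 4 of a single group, so no condition was compared with another. The labels give each library its own biosample but share 1 donor identifier, and they state neither the tissue nor the sort. The SD over the 4 libraries therefore measures the spread between these libraries, part of which may be technical. Positions are given on mm10.

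NK cells had 36614 regions that were accessible in at least 3 of the 4 libraries, here called recurrent. Of these, 12969 were promoter regions, at least partly within 1 kb of the 5' end of a protein-coding gene, and 23645 were distal regions. A recurrent promoter region was present at 10919 of the 21728 protein-coding genes on the autosomes and X (50.3%). The highest promoter signal of all genes lay at Dynlt1b, a dynein light chain gene, with 45.1 ± 12.2 (SD, n = 4) at chromosome 17, 6429981 to 6430180, a region that spans the 5' end. Other promoters among the highest 10 were Eif5a, a translation factor (24.5 ± 7.98), Sde2 (24.6 ± 6.79), Dnpep, an aminopeptidase (25.01 ± 8.18), Cyth1 (23.8 ± 7.11), Tle4, a co-repressor (23.6 ± 5.73), and Ctnna3 (24.8 ± 3.83). A single region at chromosome 13, 17694901 to 17695140, served the oppositely oriented genes Mplkip and Sugct and had a signal of 25.3 ± 7.66. Dynlt1b has near-identical neighbours and Gm21887 on X (31.4 ± 13.4) is an unnamed gene model, so reads at either may be shared with copies. The signal is the authors' own value per peak, and its scale between libraries is not given in the sources used here.

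Replicate 3 had the most peaks, 69168, against 44113 in replicate 1, 47496 in replicate 2 and 36285 in replicate 4, a mean of 49266 ± 14075 (SD, n = 4). Merging the peaks gave 78186 regions, of which 27121 (34.7%) were found in all 4 libraries and 32415 (41.5%) in 1 library. Of the single-library regions, 22365 (69.0%) came from replicate 3. With the same number of strongest peaks, 27213, taken from each library, 59.8% of merged regions were found in all 4 and 31.3% of the single-library regions came from replicate 3.

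**Figure D1:**
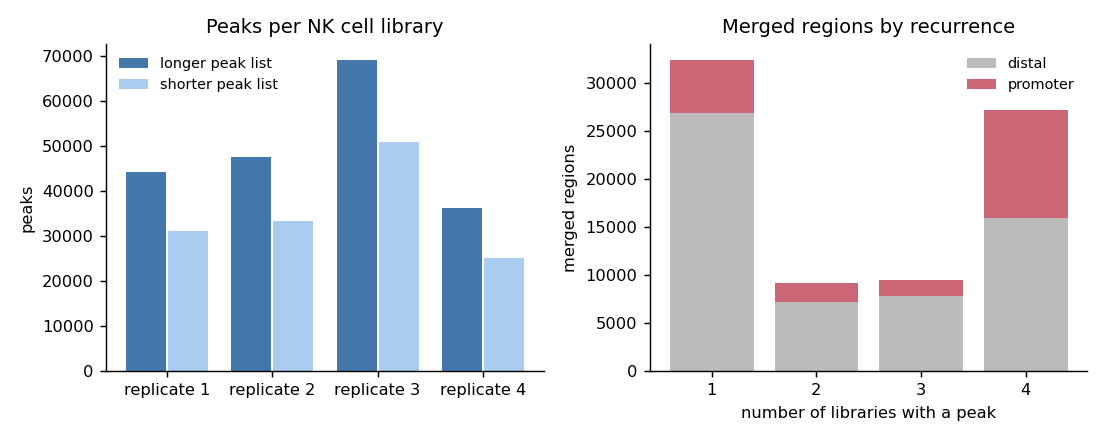
Left, number of peaks in each of the 4 NK cell libraries in the longer and the shorter of the authors' peak lists; right, number of merged regions by the number of libraries with a peak, split into promoter and distal regions. Replicate 3 reached 69168 peaks, and 27121 regions had a peak in all 4 libraries.

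The libraries resembled each other in which sites were open and in how strong they were. For a pair of libraries, 85.6% ± 2.73 (SD over 6 pairs) of the peaks of the shorter list overlapped a peak of the other by at least 1 bp, against 0.976% when peaks were shifted along the chromosomes. The lowest pair, replicates 1 and 4, shared 81.9% and the highest, replicates 1 and 3, shared 89.0%. The signal of shared regions had a Spearman correlation of 0.914 on average, from 0.894 between replicates 2 and 3 to 0.957 between replicates 1 and 2. This correlation is across regions, which are not independent replicates.

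Promoter regions were shared by the NK cell libraries more often than distal regions. Of 20472 promoter regions, 54.9% were found in all 4 libraries, against 27.5% of 57672 distal regions, a difference of 27.4 points. Promoters were higher on each of the 20 chromosomes tested, by 23.3 to 31.9 points (two-sided sign-flip permutation test over chromosomes, p = 1e-05, the smallest that the resamples can give). Promoter peaks were also stronger, with a median signal 2.52 ± 0.222 times that of distal peaks (SD, n = 4). When promoter and distal peaks of a library were matched on signal, the difference shrank from 21.5 ± 10.1 to 1.52 ± 3.70 points (SD over the 4 libraries as reference), with 18 of 20 chromosomes higher (permutation p = 5e-05). The matched difference was below 0 with replicate 4 as the reference, at -2.33 points, and 6.56 points with replicate 3.

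Genes of cytokine signalling and trafficking and of NK transcription factors had accessible promoters more often than other genes. A recurrent promoter region was present at 16 of 20 genes for cytokine receptors and trafficking (Fisher's exact test, Benjamini-Hochberg adjusted p = 0.0203) and at 14 of 18 NK transcription factor genes (adjusted exact p = 0.0463). The share among the 21486 protein-coding genes in no list was 50.3%. Cytotoxic effectors and secreted factors reached 15 of 20 and missed the threshold (adjusted exact p = 0.0552), and NK receptors and adaptors, with 10 of 22, did not differ detectably from other genes (adjusted exact p = 0.737). Over single libraries, a promoter peak was found at 85.0% ± 5.77 of the cytokine receptor and trafficking list, 80.6% ± 7.17 of the transcription factors, 82.5% ± 8.66 of the cytotoxic list and 51.1% ± 9.37 of the receptors (SD, n = 4). All 12 gene lists were fixed before the data were examined. The call for cytokine receptors was lost with the shorter peak list (adjusted exact p = 0.0534) and that for transcription factors with a 500 bp promoter window (adjusted exact p = 0.417). The cytotoxic list passed in every alternative run (adjusted exact p from 0.00104 with presence in at least 1 library to 0.0309 with the 500 bp window) except without replicate 3.

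Among NK transcription factors, the promoter of Klf2, a regulator of lymphocyte trafficking, had the highest signal, 17.1 ± 4.88 (SD, n = 4), at chromosome 8, 72318741 to 72319180. Runx3 followed with 9.28 ± 3.66 upstream of the gene at chromosome 4, 135120341 to 135120640. Id2, which is required for NK cell development, had 8.83 ± 2.51 and Bhlhe40 had 8.23 ± 2.90. No library had a peak at the annotated 5' end of Ets1 or Zfp683. In the cytokine receptor and trafficking list, Ifngr1, a chain of the interferon gamma receptor, reached 19.9 ± 5.56 at chromosome 10, 19591721 to 19592040. Cxcr4, a homing receptor, had 10.8 ± 1.51, Il2rb, a chain of the receptors for interleukins 2 and 15, had 7.73 ± 3.91 in its 5' UTR, and Il12rb2 had 5.08 ± 2.00. Cx3cr1, a chemokine receptor, had no peak at its annotated 5' end in any library.

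Among cytotoxic genes, the granule membrane gene Lamp1 had a promoter signal of 6.69 ± 1.81 (SD, n = 4) and Prf1, which encodes the pore-forming protein perforin, had 6.14 ± 2.87 at chromosome 10, 61297541 to 61297840. Nkg7, a granule protein gene, had 4.57 ± 2.13 and the chemokine gene Ccl4 had 4.32 ± 2.61. Srgn, the granule proteoglycan, was the only member with no peak at its annotated 5' end in any library. Among receptors, Ncr1, which encodes the activating receptor NKp46, had 4.45 ± 2.72 at chromosome 7, 4337601 to 4337840, a region that spans the 5' end. Fcgr3, the low-affinity IgG receptor, had 2.80 ± 0.292 in an intron, Itga2 had 2.22 ± 0.666 in a coding exon and the adaptor gene Hcst had 2.16 ± 0.553. The 8 receptor genes with no promoter peak in any library were Klra4, Klra7, Klra8, Klra9, Klrg1, Cd226, Cd160 and Slamf7. The Klra genes form a family of close copies and the Ccl genes are related, so values at single members are uncertain. The extent of this was not tested, and the receptor list was not tested again without the Klra genes.

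**Figure D2:**
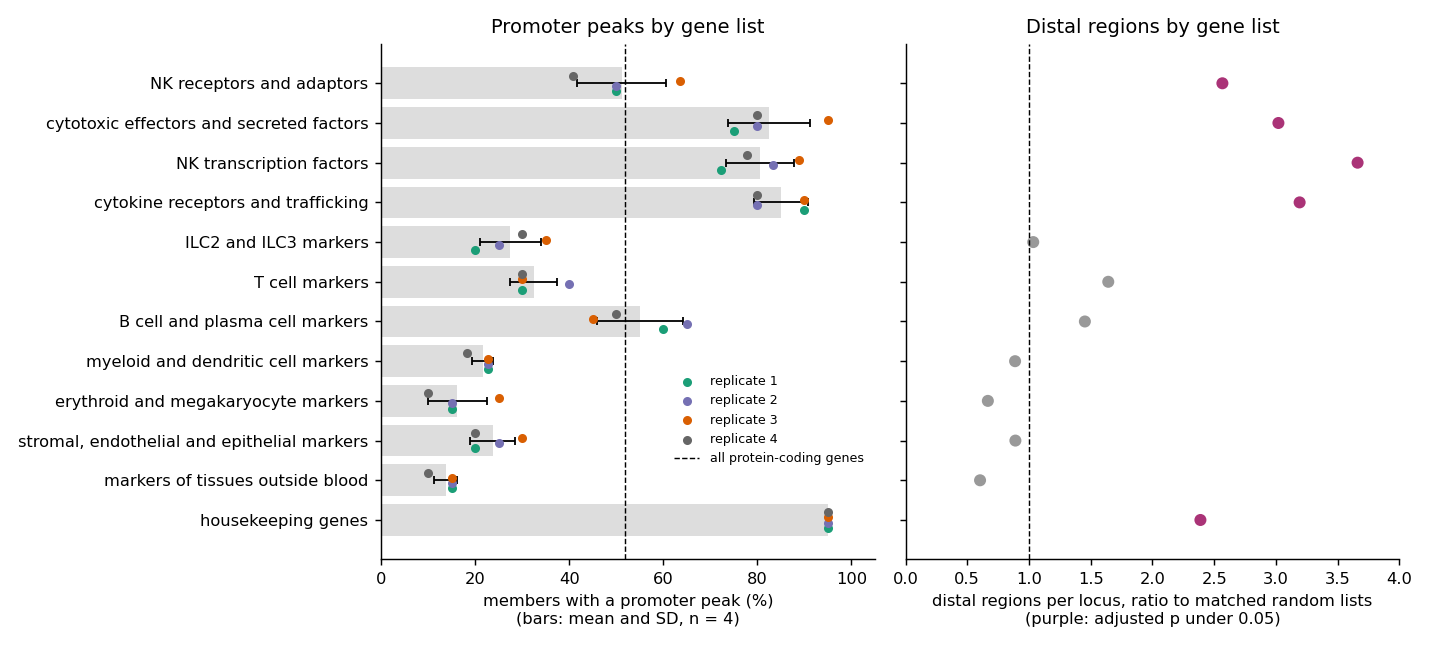
Left, percentage of each gene list with a promoter peak, as points for each of the 4 libraries and bars for the mean with the SD (n = 4), with a dashed line for all protein-coding genes; right, distal recurrent regions per locus as a ratio to matched random lists, with lists past the threshold in purple. The lists for transcription factors, cytotoxic effectors and cytokine receptors averaged 80.6%, 82.5% and 85.0% on the left and 3.66, 3.02 and 3.19 on the right.

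Promoters of genes typical of other cell types were accessible less often, except for B cell genes, and T cell genes missed the threshold. A recurrent promoter region was present at 2 of 20 stromal, endothelial and epithelial genes (Fisher's exact test, adjusted p = 0.00123), 3 of 20 erythroid and megakaryocyte genes (adjusted exact p = 0.0042), 3 of 20 markers of tissues outside blood (adjusted exact p = 0.0042), 5 of 22 myeloid and dendritic cell genes (adjusted exact p = 0.0203) and 4 of 20 genes of group 2 and 3 innate lymphoid cells (ILC2 and ILC3; adjusted exact p = 0.0165). T cell genes, with 6 of 20, missed the threshold (adjusted exact p = 0.0918), and B cell and plasma cell genes, with 10 of 20, stood at the share of other genes (adjusted exact p = 1). Of 20 housekeeping genes, 19 had one (adjusted exact p = 0.000481). With presence in at least 1 library as the criterion, the calls for stromal genes (adjusted exact p = 1) and ILC2 and ILC3 genes (adjusted exact p = 0.442) were lost. The T cell list passed the threshold, with a lower share, under the shorter peak list (adjusted exact p = 0.0112) and the 500 bp window (adjusted exact p = 0.0190), and the ILC list lost its call with any transcript's 5' end (adjusted exact p = 0.0539).

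Taken as a pool, the 80 genes of the 4 NK lists had a recurrent promoter region in 55 cases (68.8%). This share was above that of 6 of the 8 other lists, from stromal genes at 10% (Fisher's exact test, adjusted p = 1.52e-05) to T cell genes at 30% (adjusted exact p = 0.00281). It was below that of housekeeping genes at 95% (adjusted exact p = 0.0234). The difference from B cell genes at 50% did not pass (adjusted exact p = 0.126), although it did with the shorter peak list (adjusted exact p = 0.0061) and with regions found in all 4 libraries (adjusted exact p = 0.00543). The housekeeping difference was lost without replicate 1 (adjusted exact p = 0.0744) or replicate 4 (adjusted exact p = 0.0776), and with presence in at least 1 library (adjusted exact p = 0.456).

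The open promoters in the lists for other cells included several lineage regulators. Zbtb7b, a T helper lineage factor, had 9.25 ± 2.46 in an intron (SD, n = 4), and a region in the first part of Foxp3, the regulatory T cell factor, had 6.50 ± 2.14, but this region lies within 1 kb of the start of Ppp1r3f as well. Bcl11b had 1.64 ± 0.468 and Ubash3a 1.06 ± 0.345. The myeloid factor Spi1 had 3.09 ± 1.26, Cebpa 2.36 ± 0.655, Cd68 2.18 ± 0.700 and Cebpe 1.43 ± 0.545. Of the ILC list, Ahr had 1.72 ± 0.455, Icos 1.503 ± 0.979 and Kit 0.860 ± 0.265. Signals in the B cell list were low, with Ebf1, a B lineage factor, at 1.75 ± 0.668, Cr2 at 1.44 ± 0.776, Bank1 at 1.23 ± 0.170 and Pou2af1 at 0.999 ± 0.357. Outside these lineages, Tspan33 had 2.24 ± 0.630, Epor 0.739 ± 0.170, Col1a1 2.82 ± 1.14 in an intron, Ckm 3.83 ± 1.12 in an intron and Syp 1.27 ± 0.209. Housekeeping promoters were strong, with Rplp0 at 19.3 ± 2.93, Actb at 19.2 ± 5.54, Polr2a at 13.9 ± 3.27 and Ppia at 13.0 ± 2.48.

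Replicate 3 stood apart from the other libraries at NK and B cell genes. Over the 52 genes of the NK lists with a promoter peak in all 4 libraries, the median signal was 4.19 in replicate 3 and 2.19, 2.45 and 1.83 in replicates 1, 2 and 4. Over the 6 such B cell genes it was 0.519 in replicate 3 and 1.05, 1.41 and 1.21 in the others, and over the 19 such housekeeping genes it was 10.4 against 6.12, 8.17 and 8.05. A promoter peak was present at 95% of cytotoxic genes and 63.6% of NK receptor genes in replicate 3, against at most 80% and 50% in the other libraries, and at 45.0% of B cell genes, against 50% to 65%. For NK transcription factors the share was 88.9% in replicate 3 against at most 83.3% in the others. Cytokine receptor and trafficking genes reached 90% in both replicates 1 and 3. Without replicate 3, 3 lists were above the other genes and 5 below. With 4 libraries, an exact test of 1 library against 3 cannot pass 0.05, so none was made.

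**Figure D3:**
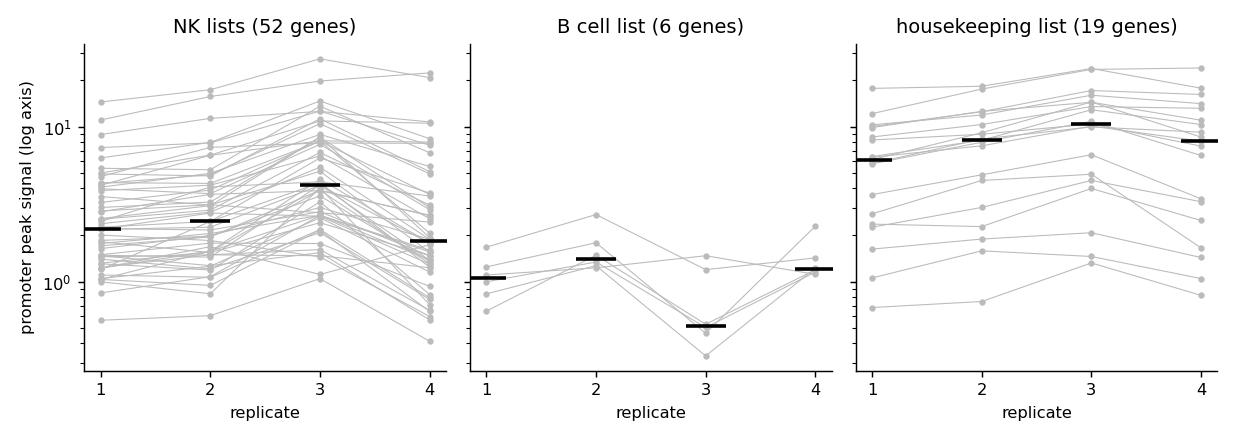
Promoter peak signal on a log axis in each library for genes with a peak in all 4 libraries; each line is 1 gene and black dashes are medians. The median of the 52 NK list genes is highest in replicate 3, at 4.19, and that of the 6 B cell genes is lowest there, at 0.519.

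Distal accessible regions were concentrated around NK cell genes. Within the gene body and 25 kb on either side, NK transcription factor genes had 7.17 distal recurrent regions per locus, 3.66 times the number in random gene lists matched on locus length (permutation test with 10000 lists, adjusted p = 0.00768). The ratio was 3.19 for cytokine receptors and trafficking, 3.02 for cytotoxic effectors and 2.57 for NK receptors (adjusted permutation p = 0.0008 each, from the smallest p that the lists can give). Housekeeping genes also exceeded random lists, at 2.39 (adjusted permutation p = 0.0018). T cell genes, at 1.64 (adjusted permutation p = 0.112), and B cell genes, at 1.45 (adjusted permutation p = 0.243), did not pass, nor did the ILC list at 1.03, stromal genes at 0.890, myeloid genes at 0.887, erythroid genes at 0.667 or markers outside blood at 0.604. With the gene body alone, the calls for NK receptors (1.95, adjusted permutation p = 0.275) and cytotoxic effectors (2.02, adjusted permutation p = 0.277) were lost. Flanked loci of neighbouring list members, such as Ccl3 and Ccl4, overlap, so a distal region can count for several members of a list. The random lists were matched on locus length and not on such clustering, so the permutation p-values do not allow for it.

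Runx3 had 14 distal regions, Runx1 13, Ets1 11 and Tox 10, in loci of 107 kb, 275 kb, 172 kb and 355 kb. The receptor gene Klrb1c, which encodes the NK1.1 antigen, had 13 distal regions but a promoter peak in replicate 3 alone, and Fcgr3 and Klrg1 had 8 each and Slamf7 had 7. Among cytotoxic genes, Srgn had 10 and Prf1, Fasl and Ccl3 had 9 each. In the cytokine receptor and trafficking list, Cx3cr1 had 11, Il2rb and Il18r1 had 9 each and Tgfbr2 had 8. Klrg1, Slamf7, Srgn, Ets1 and Cx3cr1 thus combined distal regions with no peak at the annotated 5' end. Distal was defined by the annotated 5' end of the gene, so a region at another transcript start can count as distal. Slamf7, Srgn and Ets1 had a recurrent region at such a start. The distal counts were not repeated without such regions. Over all protein-coding genes, the count was highest at Gm20388 (178), an annotated gene with a locus of 4485 kb that runs through its neighbours, followed by Gse1 (35), Fgfr2 (30), Prex1 (26), Foxp1 (25) and Arhgef3 (21). Gse1 lies within Gm20388, so its regions count for both. The annotated locus of Fgfr2 is 3011 kb long, and these counts were not divided by locus length. Camta1, Arid1b, Nav2 and Gm44511 had 20 each, and the locus of Gm44511 overlaps that of Klrb1c. Prex1, a guanine exchange factor for Rac, and Camta1 also had strong promoters, 10.6 ± 5.22 and 14.6 ± 3.65 (SD, n = 4), whereas Gse1 had no promoter peak and Arhgef3 had one in replicate 3 alone.

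Distal regions of NK cells were rich in motifs of RUNX, ETS, T-box and CTCF factors, which were among 20 enriched motifs. The motif of CTCF, the insulator protein, occurred in 12.7% of 23626 distal windows of 150 bp and in 0.123% of windows matched on GC content and chromosome, a fold of 103. RUNX motifs were 4.40-fold enriched (5.09% against 1.16%), ETS motifs 4.45-fold (6.34% against 1.43%), PU.1 motifs 5.19-fold and T-box motifs, the class bound by T-bet and Eomes, 2.17-fold (1.59% against 0.732%). The PU.1 and ETS sequences used share the stretch AGGAAGT, so their folds do not separate these factors. Of 28 motifs tested, 20 were enriched and 3 depleted (Fisher's exact test, Benjamini-Hochberg adjusted p of at most 0.0357). Per library, the fold was 4.89 ± 0.846 for RUNX, 4.33 ± 0.652 for ETS, 4.45 ± 0.488 for PU.1, 2.00 ± 0.367 for T-box and 125 ± 19.5 for CTCF (SD, n = 4). NRF1 (8.40), CREB (5.50), AP-1 (2.21), IRF (2.04) and SP/KLF (2.01) motifs were enriched as well. So were C/EBP (4.33, from 13 against 3 windows), MEF2 (3.47), octamer (1.79), NFIL3 (1.75), E-box (1.70), FOXA (1.56), NF-kB (1.25), TCF/LEF (1.23), E-protein (1.16) and NEUROD (1.12) motifs. TEAD (0.644), NFY (0.814) and ZEB (0.955) motifs were depleted. STAT (1.15), GATA (1.07), EBF (1.03) and HNF4 (0.822) motifs did not pass, and no window of either set held the HNF1 motif.

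The background and the set of regions used decided some of the motif calls. Against windows 1 kb to either side of the same regions, NFIL3 turned to a fold of 0.678 and GATA to 0.792, while ZEB rose to 1.30 and NFY to 1.21. In the same comparison octamer (0.947) and FOXA (0.984) fell below 1, and IRF (1.06), TCF/LEF (1.01) and MEF2 (1.40) no longer passed. In regions found in all 4 libraries, C/EBP (3.33), TCF/LEF (1.26), NEUROD (1.08) and NFY (0.931) did not pass, although the TCF/LEF fold was no lower than over all recurrent regions, and EBF was depleted (0.681, adjusted exact p = 0.0157). GATA passed, enriched, without replicate 1, 3 or 4 (1.10, 1.12 and 1.10) and STAT without replicate 2 (1.22). TCF/LEF did not pass without replicate 2 (1.10) or 3 (1.13) or in 300 bp windows (1.10), nor ZEB without replicate 3 (0.979) or 4 (0.967). Distal windows can include starts of other transcripts of a gene, and the motif folds were not recomputed without them.

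**Figure D4:**
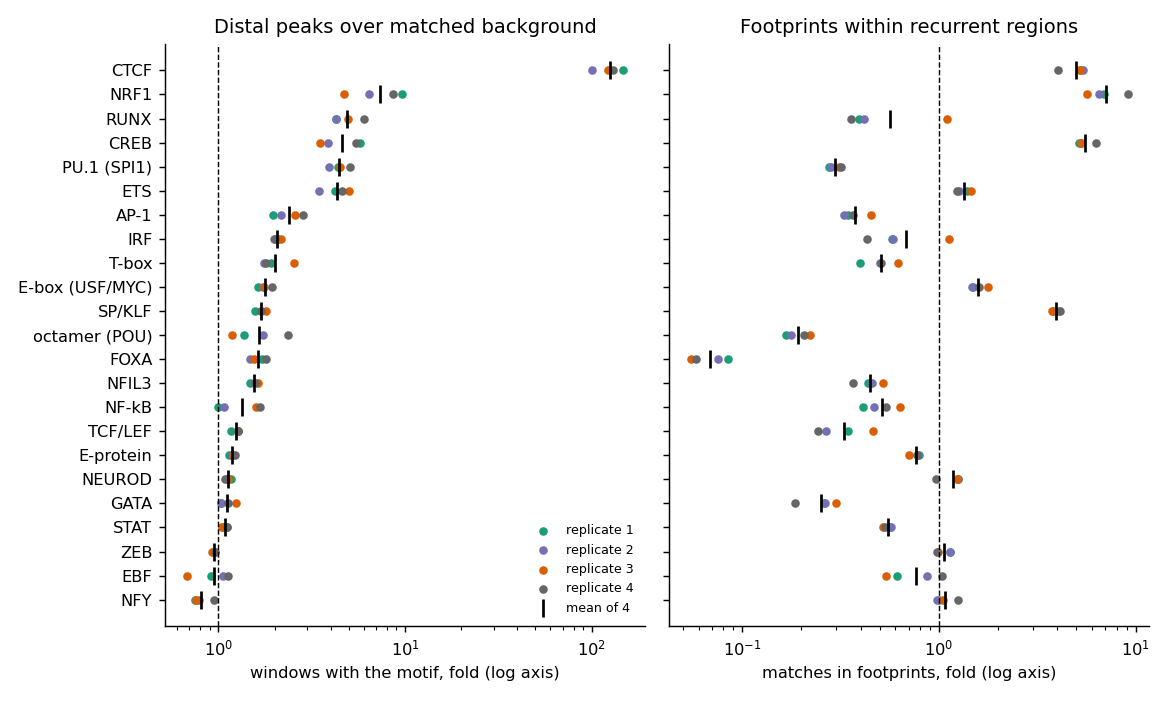
Fold for each motif with at least 100 matched distal windows, per library (points) and as the mean of 4 (bars), on log axes; left, distal peak windows against matched background windows, right, share of motif matches inside footprints against the share of bases. CTCF has the highest mean on the left, at 125, and NRF1 on the right, at 7.04.

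Footprints, short stretches protected from cutting within accessible DNA, were found most often on motifs of NRF1, CREB, CTCF and SP/KLF factors. The libraries held 115795, 127261, 185155 and 96002 footprints in replicates 1 to 4, a mean of 131053 ± 38309 (SD, n = 4), and 83.9% ± 1.14 of them lay in peaks. Footprints covered 12.4% ± 2.70 of the bases of recurrent regions. The share of NRF1 matches lying at least 80% within a footprint was 7.04 ± 1.47 times that base share, and the ratio was 5.49 ± 0.514 for CREB, 4.97 ± 0.639 for CTCF and 3.93 ± 0.196 for SP/KLF. C/EBP (1.98 ± 0.267), E-box (1.59 ± 0.139) and ETS (1.34 ± 0.103) were also above 1 in all 4 libraries, 7 motifs in total. The base share was taken over promoter and distal regions together. Motif matches were not matched on signal or kind of region, so differences in these between motifs are not taken out. An exact sign-flip test over 4 libraries cannot pass 0.05, so no p was computed.

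By the same criterion, T-box and RUNX motifs lay in footprints less often than the bases of these regions did in most libraries. T-box matches had a ratio of 0.507 ± 0.0911 and RUNX matches 0.566 ± 0.355, where replicate 3 had 1.10 and the others 0.358 to 0.418. The FOXA ratio was 0.0682 ± 0.0142. With 1 bp of overlap counted, 21 motifs were above 1 in all 4 libraries, among them T-box at 1.17 ± 0.173 and RUNX at 1.72 ± 0.458. Both ratios are biased by the length of a motif, since a whole match lies in a footprint less easily than a single base and touches one more easily, so a ratio below 1 at 80% or above 1 at 1 bp is expected without any association. Set, at 80%, against positions of the motif's own length, a comparison chosen after the data were seen, T-box stayed below 1 in all 4 libraries at 0.777 ± 0.129 and RUNX in 3 of them at 0.861 ± 0.521. In that comparison 10 motifs were above 1 in all 4 libraries, with NRF1 at 11.2 ± 2.73, CTCF at 9.83 ± 0.888, CREB at 8.44 ± 0.994, SP/KLF at 7.04 ± 0.576 and ETS at 2.05 ± 0.129. For a pair of libraries, 54.0% ± 3.45 (SD over 6 pairs) of the footprints of the shorter list had a counterpart overlapping by at least 50%. Within shared peaks 57.8% ± 2.30 did, against 23.6% ± 1.78 when footprints were shifted along those peaks joined end to end. Such a shift moves footprints into other peaks, so it keeps neither their number per peak nor their place within a peak.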

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

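The tests on promoters of B cell and T cell genes and on Y-linked genes, the count of distal B cell regions absent from replicate 3 and the use of a bootstrap interval for the distal B cell loci were chosen only after the results were seen. Of 144 values compared across the 4 libraries, 21 had 1 library far from the other 3, where chance gives about 1 in 20, or 7.2, for independent values on a continuous scale. These values are not independent, and in 6 of the 21 the other 3 libraries were equal, which flags any difference, so 21 against 7.2 does not measure an excess over chance. Replicate 3 was the highest library in 11 of the 21 and the lowest in 1. No biological explanation was tested as a difference between groups, because the design has a single group, and cells of another type or sex are weighed below as admixture.

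Promoter signals of NK list genes with replicate 3 far above the rest were 8.52 at Ncr1 (others 3.01 to 3.26), 10.4 at Prf1 (4.29 to 4.96), 12.6 at Id2 (7.32 to 7.84), 11.2 at Runx1 (4.80 to 5.12) and 8.04 at Il12rb2 (3.65 to 4.35). Klrb1c had a signal of 2.67 in replicate 3 and no promoter peak in the other libraries. Outside the NK lists, replicate 3 stood apart at Ahr (2.40), Ubash3a (1.57), Rplp0 (23.7) and Arhgef3 (0.490, with no peak in the others). Its median peak signal, 0.922, was the lowest of the 4 libraries, and its footprint ratio for RUNX motifs, 1.10, the highest.

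Relative to other promoters of like signal, B cell promoters were lower in replicate 3 than in the other libraries, with a median log2 ratio of -1.84 over 8 genes, all of them below 0. A region without a peak in replicate 3 was given the lowest peak signal of that library, so this median is not a measured fold throughout, and over the 6 genes with regions found in all 4 libraries it was -1.49. The median over 8 genes is under each of 10000 random gene lists (percentile 0.00). This argues against stronger enrichment or more reads in that library as the only account of the B cell promoters. The random genes were not chosen by signal, however, so any wider scatter of weak promoters is not allowed for. At distal regions of 13 B cell loci the median was -0.28, at percentile 4.14, which misses the limit of 2.5 set beforehand for fewer B cells and stays inside the range set for enrichment or reads, but the bootstrap interval of the median, -0.65 to -0.04, includes the limit of -0.30, so by this median the 2 explanations cannot be told apart there. Of 39 distal regions at these loci found in the other 3 libraries, 4 were absent from replicate 3, at 4 loci. From regions elsewhere of like signal, 0.417 were expected (permutation test with 10000 draws of regions, p = 0.0014). This argues against enrichment or reads alone for these 4. The count was made for B cell loci only, so it does not set them apart from loci of other lists. Fewer cells of every type other than NK cells is not supported by promoters of the other lists, with medians of 0.13 for T cell genes (5 genes, percentile 84.6), 0.35 for ILC genes (3 genes, percentile 97.54) and 0.39 for myeloid genes (4 genes, none below 0, percentile 99.3, adjusted permutation p = 0.027). It stays open all the same, because only 2 T cell and 0 myeloid genes are as low in signal as the B cell ones, and a strong promoter would hide the loss of a small share of cells. The test first planned for this, on distal regions, put T cell loci at a median of 0.11 (16 genes, 6 below 0, percentile 94.2). Myeloid loci lay at -0.20 (10 genes, 9 below 0, percentile 13.95), opposite in sign to the myeloid promoters. That test required B cell loci below percentile 2.5 and so did not decide. A lower share of B cells in replicate 3 is thus a hypothesis only, and the labels name no sort or gate that would remove B cells.

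The B cell genes with the strongest promoters did not all move alike. Ebf1 had 1.20 in replicate 3 against 1.42 to 2.71 in the others and Cr2 had 0.465 against 1.25 to 2.28, whereas Bank1 had 1.47 against 1.10 to 1.23. Of 13 B cell list genes with a promoter peak in at least 2 of the other 3 libraries, 5 had none in replicate 3, against 1 of 7 T cell genes and 0 of 5 myeloid genes. Distal loci of erythroid, stromal and non-blood genes lay low as well, at percentiles 4.60, 5.63 and 6.50, none past the adjusted threshold. Over regions found in all libraries, replicate 4 was low too at stromal (-0.27, replicate 3 -0.28) and non-blood loci (-0.26, replicate 3 -0.35). At erythroid loci it was near the rest (-0.04, replicate 3 -0.23). At distal regions, NK receptor, cytotoxic, transcription factor and cytokine receptor loci were higher in replicate 3, with medians of 0.59, 0.46, 0.26 and 0.22 (permutation test with random lists, adjusted p = 0.0012, 0.0012, 0.0192 and 0.0204). At promoters, the receptor, cytotoxic and cytokine receptor lists passed as well, with medians of 0.79, 0.69 and 0.39 (same test, adjusted permutation p = 0.00045 each). Transcription factor promoters did not (0.11, adjusted permutation p = 0.152).

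Replicate 3 also held 22363 regions on the autosomes and X that no other library had. Calls at background positions are argued against by the 19721 distal ones among them, in which T-box motifs, the lowest of the 3 motif classes tested, were 2.72-fold enriched over matched windows, RUNX motifs 5.42-fold and ETS motifs 5.10-fold. Weaker sites that only this library had the reads or enrichment to detect are consistent with their median signal of 0.440, at percentile 1.01 of the signal of regions found in all 4 libraries (median 2.85), although a low signal is also close to built in for regions that other libraries missed. With 27213 peaks per library the share of single-library regions from replicate 3 fell to 31.3%, from 69.0%. CTCF motifs were 41.1-fold and EBF motifs 0.511-fold in these regions; whether this makeup differs from that of shared regions was not tested.

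On chromosome Y, 42 merged regions had peaks although all libraries are labelled female. Male cells are argued against by the Y-linked genes Kdm5d, Eif2s3y, Uty and Ddx3y, of which 0 had a promoter peak in any library, while their 4 partners on X each had one in all 4 libraries. Sequence shared with other places in the genome is a candidate explanation, since 88.1% of the 42 regions consisted mostly of 31-mers present more than once in the genome, against 3.20% of 500 autosomal regions.

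Replicates 1, 2 and 4 stood apart in 9 values. Replicate 1 had the widest peaks, with a median of 210 bp against 200 bp, and the lowest distal TCF/LEF fold, 1.17. Replicate 2 had a promoter peak at 40% of T cell genes against 30% in the others. Replicate 4 had the lowest share for myeloid genes, 18.2%, and for markers outside blood, 10%. It also had the highest distal NFY fold, 0.944, the lowest footprint ratios for CTCF, 4.03, and NEUROD, 0.971, and the highest for CREB, 6.26.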

How the results depend on the processing

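Matching on signal, 5' ends of all genes, any transcript's 5' end for sharing and the motif-length expected share were chosen after the data were seen. Of 131 repeats of the overall results under 25 alternatives, 16 moved. Only the difference in sharing between promoter and distal regions could be labelled as changing direction, and its overall value did not. The other 115 stayed within the limits set, which were the same side of the threshold for a test, 1.5 times for a count and the SD for a value. Leaving out a replicate cannot shift a mean over the libraries by its SD, so such repeats were bound to stay. The share of merged regions found in all libraries had a limit of 15.8 points, the SD of a related share per library. Its rise from 34.7% to 48.3% without replicate 3 therefore counted as unchanged. The 115 are thus no measure of stability. A count can stay while its members change, as with the shorter peak list, where the cytotoxic list gained a call and cytokine receptors lost theirs. Where no cause is named, it was not tested. Promoter regions were shared more often than distal ones in each setting run, but matching on signal took the difference per reference library from 21.5 to 1.52 points, and to -2.33 with replicate 4 as the reference. The number of reads is not given, so no setting could adjust for it, and a stricter footprint threshold could not be run because the footprint lists hold a single value.

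With the shorter peak list, peaks per library fell to 35056 by construction, pairwise overlap rose to 90.5% and the pooled NK share was 60%. With 27213 peaks taken from each library, 59.8% of merged regions were found in all libraries and 23476 were recurrent. Reciprocal overlap of 50% gave 70.2%. The pooled NK share was 77.5% with a 2.5 kb window, 76.3% with any transcript's 5' end, 85.0% with presence in at least 1 library and 68.8% to 76.3% leaving out 1 replicate, where recurrence required fewer libraries. Presence in at least 1 library left 3 lists with fewer open promoters, and the gene body alone left 3 lists with more distal regions. Footprint overlap was 59.2% with 1 bp and 46.4% with 80%, and 21 motifs exceeded 1 when 1 bp sufficed.

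Among results with a test, each change of direction concerned a value that had not passed its test in the chosen setting, except those of NFIL3, octamer, FOXA, ZEB and NFY motifs. B cell promoters moved to 1.83 points (2.5 kb), 1.64 (500 bp), 5.29 (any transcript), 13.4 (at least 1 library) and 3.11 to 14.3 without 1 replicate, and NK receptors to 1.38 (2.5 kb), 7.08 (at least 1 library) and -5.22 to 2.65 without 1 replicate. The ILC locus ratio was 0.989 with regions found in all 4 libraries and 0.922 with a 50 kb flank, myeloid loci 1.14 with 50 kb, and stromal and non-blood loci 1.23 and 1.17 with no flank. EBF motifs had 0.681 in regions found in all 4, 0.975 in 300 bp windows and 0.863 to 1.06 without 1 replicate, and HNF4 0.705 to 1.15. Against windows 1 kb to either side, STAT had 0.942, NFIL3 0.678, GATA 0.792, ZEB 1.30, NFY 1.21, octamer 0.947 and FOXA 0.984. Footprint ratios, which have no test, depended on the criterion. With 1 bp of overlap, which a motif reaches more easily than a single base does, T-box (1.17), RUNX (1.72), PU.1 (1.42), AP-1 (1.23), NF-kB (1.99), IRF (1.75), STAT (1.48), NFIL3 (1.10), TCF/LEF (1.14), EBF (1.95), E-protein (1.17), octamer (1.37), HNF4 (1.64) and MEF2 (1.62) rose from a mean below 1 to one above it, and with the motif-length expected share IRF (1.07) and EBF (1.22) did. Of 711 repeats of distal region counts at named genes, 562 stayed within 1.5 times, and of 632 of promoter signals, 511 moved by less than the SD. Leaving out a replicate could not shift a mean signal by the SD, so those repeats were bound to stay. A gene with no promoter peak in any library was counted as moved even where its signal did not change. The 511 are therefore no measure of stability.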

Other observations

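The X chromosome had fewer peaks per length than the autosomes, 7.36 ± 1.81 against 19.5 ± 5.59 per Mb (SD, n = 4), in each of the 4 libraries. Xist, the RNA gene of X inactivation, had a promoter signal of 0.957 ± 0.215. Kdm6a, a histone demethylase gene on X, reached 15.1 ± 4.89, Kdm5c 9.36 ± 3.09, Eif2s3x 6.56 ± 2.06 and Ddx3x 5.91 ± 1.20. The difference between chromosomes was not tested.

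Several genes without a recurrent region at their annotated 5' end had one at the start of another annotated transcript. Among NK lists these were Ets1, with a signal of 9.69 ± 2.06 (SD, n = 4), Serpinb9 (3.29 ± 0.689), Srgn (2.80 ± 1.27), Zeb2 (1.35 ± 0.410), Cd160 (0.559 ± 0.440) and Slamf7 (0.508 ± 0.341). In the T cell list they were Cd3d, a chain of the T cell receptor complex (6.95 ± 2.89), Cd28 (3.68 ± 2.07) and Camk4 (0.891 ± 0.194), and in the ILC list Gata3 (3.69 ± 2.30) and Rora (2.81 ± 0.321). The platelet integrin gene Itga2b had 5.99 ± 1.51 and the housekeeping gene Ywhaz 13.0 ± 4.12. An absent promoter peak in the gene-level count therefore does not mean that each start of the gene was closed.

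Motif enrichment was also computed in the regions found in 1 library only. In 3163 distal regions of replicate 2 only, CTCF motifs were 27.0-fold (Fisher's exact test, adjusted p = 1.77e-19), PU.1 motifs 3.25-fold (adjusted exact p = 0.00175), EBF motifs 2.5-fold (adjusted exact p = 0.0206), ETS motifs 1.77-fold (adjusted exact p = 0.0127) and E-protein motifs 1.31-fold enriched (adjusted exact p = 0.00175), while T-box motifs did not pass (0.720). In 1987 distal regions of replicate 4 only, ZEB motifs were 1.30-fold (adjusted exact p = 0.000764), AP-1 motifs 2.06-fold (adjusted exact p = 0.00521) and ETS motifs 2.38-fold enriched (adjusted exact p = 0.00642), and CTCF motifs, in 3 windows against 1, did not pass. In 1993 distal regions of replicate 1 only, CTCF motifs were 39.0-fold enriched (adjusted exact p = 1.75e-09), and RUNX, ETS and T-box motifs did not pass. The differences between libraries were not tested.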
